A study of Mus musculus with 2 samples.

How the data were processed

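Gene expression was measured by RNA sequencing of oocyte pools. Per the labels' protocols, RNA of 100 oocytes per group went into libraries made with a NEB Ultra RNA kit and sequenced on an Illumina HiSeq. The deposited table gives FPKM values, in which the authors scaled fragments to transcript length and to the number of mapped fragments, per the file's name. Per the submitters' processing notes, Bowtie2 2.2.5 and RSEM were used with the mouse build mm9. The table itself has the header layout of a Cufflinks tracking file and places its genes on accessions of the pig chromosomes; the program, the annotation and the build behind it are not given in the sources used here. Of its genes 1900 lie beyond the last annotated gene of the longest mouse chromosome (GRCm38 annotation), and 3841 lie on unplaced scaffolds. Start positions were raised by 1 because the loci count from 0. Loci can span merged genes: 11620 genes share an identical locus with another, 1182 of them among the genes analysed, and how reads were divided there, or whether strand was used, is not given.

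The column named Con1 was matched to the control sample and SPD1 to the SPE sample, by name and number alone, although the sample labels name the mouse. 2 further columns, named Con2 and SPD2, matched no sample used here and entered no computed result. The only statements drawn from them concern GDF9: its order, and its wide difference between Con1 and Con2. Both are given without values, as a limit. By their names they may be second replicates of the same groups. Their summaries, correlations, highest genes and values for a few genes, GDF9 among them, were looked at before the tests of explanations were chosen. Each group therefore had 1 matched library, no replicate error was estimated, and no test between groups or p-value was computed. Short gene models, and listed zeros for genes that cells use generally, such as RPL29, limit what single values show. 24 gene names had turned into dates in the table and were kept as they stood. The FPKM columns sum to 249340 in the control and 251829 in the SPE library, and the 10 highest genes hold 62.9% and 64.4% of these sums. The ribosomal RNA rows hold 4.78% and 3.36%. Read counts are not in the columns analysed, so the precision per gene cannot be given. Relative depth was examined in genes between 0.005 and 0.3 FPKM in both libraries: 751 of 5128 (14.6%) lay within a relative tolerance of 0.001 of the most frequent ratio of 1.026 or of its simple multiples by 1:2, 2:1, 2:3, 3:2, 1:3 and 3:1. The effect of this processing is that FPKM is relative: a gene group that takes more of the library lowers the values of the others.

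Differences were computed as log2((SPE + 1) / (control + 1)), with a pseudocount of 1 FPKM, which understates differences of low genes. Genes with a mean of at least 1 FPKM over both libraries were kept, and those at or beyond 2-fold were counted. The text names the 12 genes with the largest positive and the 12 with the most negative ratio among genes of at least 10 FPKM with an established symbol, and up to 4 members of each list: its highest gene and those with extreme ratios. For somatic, blood and immune lists the highest member is named even under 1 FPKM. BMP15, H1FOO, ODC1 and EIF5A lie outside this rule and were added after their values were seen, as were KDM1A, CHERP and RN18S, which share a locus with a named gene. Robust SDs are the median absolute deviation scaled to a normal SD.

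33 gene lists were fixed before the data were examined, as were the size rule, the naming rule and most alternatives. Mouse symbols were matched ignoring case; 1004 genes were found and 366 had a mean of at least 1 FPKM. For each list with at least 5 measured members, the median log2 ratio was ranked among 10000 random lists of the same size, drawn with replacement from genes of the same level (20 bins of mean FPKM). A rank below 2.5% or above 97.5% was called standing apart, as a description of these libraries. The median and mean differed in sign for 3 lists, and both are printed there.

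Alternatives covered pseudocounts of 0.1 and 5 FPKM, no filter or a minimum of 10 FPKM, median or trimmed mean centring, scaling to TPM or by the upper quartile, a running median over 201 genes, and 1.5-fold and 4-fold rules. The calculations were tested on simulated data made from the means of the real genes, with 200 genes changed 4-fold (2 on the log2 scale). For SPE against control with noise of 0.2 on the log2 scale and 4320 genes passing the filter, 93.8% of the changed genes were recovered, 100% of those of at least 10 FPKM, and 0 unchanged genes were called. This checks the calculation only and gives no rate of false calls in the real data. The simulated noise was even across levels and held no zeros, whereas the real log2 ratios had an SD of 0.50. Of 200 random lists of 15 genes from the 4391 analysed 3.5% stood apart, and such a list shifted by 0.5 reached percentile 100. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.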

Results

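The data were a single table of gene expression from oocytes, the female germ cells, in a series on spermidine and the meiotic maturation of porcine oocytes. Spermidine is a natural polyamine. 2 libraries could be matched to labelled samples: a control library and a library labelled SPE, named SPD in the table and read here as the spermidine-treated one. RNA was taken from pools of 100 oocytes per group, per the labels. The sample labels named the mouse as the species, whereas the table listed genes on pig chromosomes up to position 315308402, beyond the last annotated gene of the longest mouse chromosome at 195323493. The genome build of its positions is not given in the sources used here. The values below were therefore read as pig gene models, and their link to the labelled samples rests on the column names and numbers alone.

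The table held FPKM values for 38817 genes, of which 23895 carried provisional LOC names. In the control library 14556 genes had a value above 0 and 4351 reached 1 FPKM, against 16031 and 4444 genes in the SPE library. The absolute depth is unknown, because the table gives no read counts. Among 5128 genes between 0.005 and 0.3 FPKM in both libraries, the most frequent ratio of SPE to control was 1.026, held by 227 genes within a relative tolerance of 0.001. This does not settle the relative depth, as the SPE library also had more genes above 0. With 1 matched library per group no replicate error was estimated, and the differences below compare these 2 libraries and have no test.

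The comparison implied by the series title was between oocytes matured with and without spermidine. Most genes analysed were at similar levels in both libraries. The log2(FPKM + 1) values correlated across all genes with Pearson's r = 0.98 and Spearman's rho = 0.83, where genes are not independent replicates. Only 17607 of the 38817 genes had a value above 0 in either library, so shared zeros enter these values. Over the 4391 genes with a mean of at least 1 FPKM, Pearson's r was 0.96 and Spearman's rho 0.90. Of 4391 genes with a mean of at least 1 FPKM, 4172 (95.0%) differed by less than 2-fold, 125 were at least 2-fold higher in the SPE library and 94 at least 2-fold lower, on the log2(FPKM + 1) scale. Provisional names made up 161 of these 219 genes, against 1361 of all 4391, so the genes beyond 2-fold lay mostly in provisional gene models. A zero in 1 library accounted for 38 of the higher and 35 of the lower genes, and such zeros may be failed estimates. The median log2 ratio was -0.04. The share of genes beyond 2-fold was 7.90% at 1 to 2 FPKM and 1.32% at 30 FPKM or more.

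**Figure D1:**
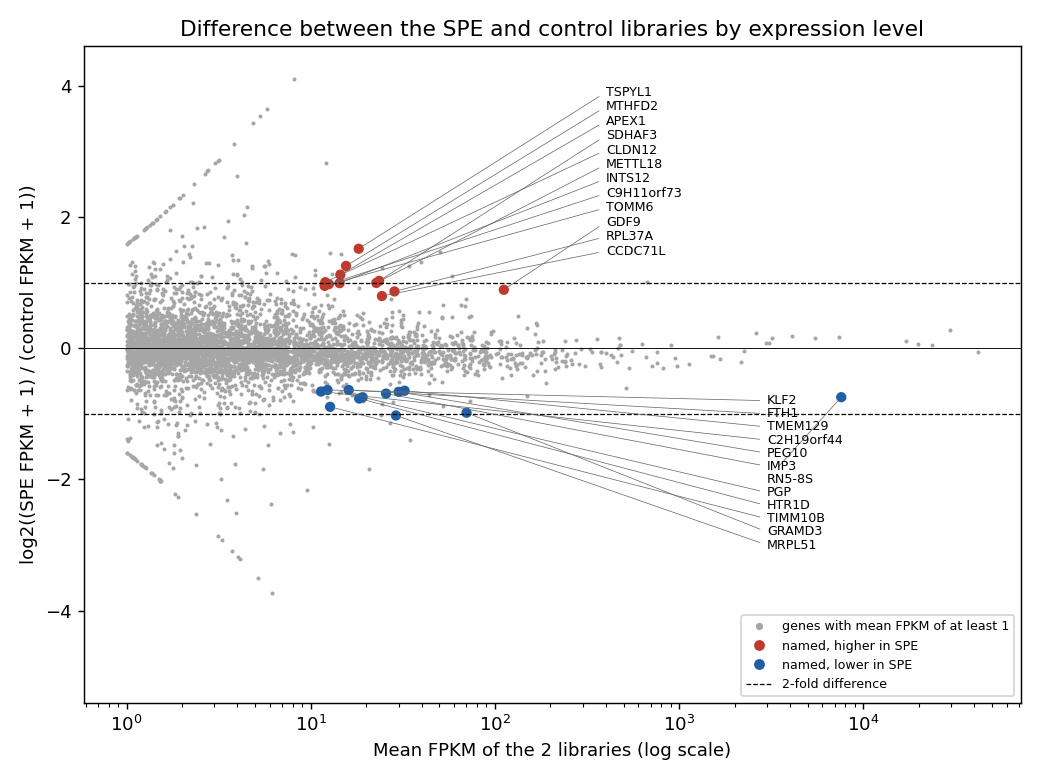
Each point is 1 of 4391 genes, with its mean FPKM in the 2 libraries on a log axis and the log2 ratio of SPE to control with a pseudocount of 1 FPKM; the dashed lines mark 2-fold. The cloud narrows with level, the diagonal edges are genes listed at 0 in 1 library, and TSPYL1, at 1.52, is the highest of the 24 labelled genes, all of at least 10 FPKM.

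Among 769 genes with an established symbol and a mean of at least 10 FPKM, 5 were at least 2-fold higher in the SPE library, 1 was at least 2-fold lower and 763 differed by less. TSPYL1, a nucleosome assembly protein family member on chromosome 1 (92021582 to 92025154), had the largest difference, from 8.96 FPKM in the control to 27.5 FPKM in the SPE library (log2 ratio 1.52). MTHFD2, the mitochondrial folate enzyme on chromosome 3 (71978927 to 71981054), was at 8.78 FPKM in the control and 22.3 FPKM in the SPE library (1.25). APEX1, the main endonuclease of base excision repair, on chromosome 7 (83479687 to 83481839), was at 8.76 and 20.2 FPKM (1.12). SDHAF3, an assembly factor of succinate dehydrogenase, was at 15.2 and 31.9 FPKM (1.03), and the tight junction gene CLDN12 was at 7.64 and 16.4 FPKM (1.01). For scale, the robust SD of the log2 ratio over all genes between 10 and 30 FPKM was 0.21. At 10 FPKM or more it was 0.33 for gene models under 3 kb, such as those of MTHFD2, APEX1 and SDHAF3, and 0.18 for longer ones. These are spreads across genes in 1 pair of libraries, not the error of a single gene. They also leave out the tails: 2.81% of genes between 10 and 30 FPKM lay at or beyond 2-fold.

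The next genes in the same direction stayed just under 2-fold on this scale. The histidine methyltransferase gene METTL18 had a log2 ratio of 0.99, the Integrator subunit gene INTS12 0.99, C9H11orf73 0.98 and TOMM6, a small subunit of the mitochondrial outer membrane translocase, 0.95. GDF9, the oocyte-secreted growth factor of the follicle on chromosome 2 (140650007 to 140652964), was at 78.1 FPKM in the control and 145 FPKM in the SPE library (0.89). This order did not hold in the unmatched columns Con2 and SPD2, which entered no computed result. There GDF9 was higher in Con2 than in SPD2, and its values in Con1 and Con2 differed widely. For the other differences reported, whether they hold in those columns was not analysed here, so the same limit applies to them. The ribosomal protein gene RPL37A, over a model of 344 bases, followed with 0.86 and CCDC71L with 0.79. No other gene of the table overlapped the loci of TSPYL1, MTHFD2, APEX1 or GDF9, whereas those of TOMM6 and CCDC71L were shared with provisional genes.

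On the lower side, MRPL51, a mitochondrial ribosomal protein gene on chromosome 5 (66630184 to 66630515), was at 39.2 FPKM in the control and 18.8 FPKM in the SPE library (log2 ratio -1.03). Its gene model spans 332 bases. It was the 1 gene at least 2-fold lower among the 769. GRAMD3 was at 93.5 and 46.8 FPKM (-0.98), and TIMM10B, of the mitochondrial inner membrane import machinery, at 16.9 and 8.62 FPKM (-0.89). The serotonin receptor gene HTR1D had a ratio of -0.77 over a locus shared with KDM1A. The phosphoglycolate phosphatase gene PGP was at -0.75, the small nucleolar ribonucleoprotein gene IMP3 at -0.69 and the retrotransposon-derived imprinted gene PEG10 at -0.67. RN5-8S, the 5.8S ribosomal RNA, was at 9512 and 5669 FPKM (-0.75), while RN18S of the same locus was at 2394 and 2804 FPKM. C2H19orf44 had -0.66 over a locus shared with CHERP, TMEM129 had -0.65, and the ferritin heavy chain gene FTH1 and the transcription factor gene KLF2 had -0.64 each. The loci of GRAMD3 and FTH1 also overlapped provisional genes.

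Of 12 measured oocyte identity genes none differed by 2-fold on the log2(FPKM + 1) scale, and GDF9 had the largest ratio. The list median was 0.02, at percentile 85.5 of 10000 random lists matched on expression. BMP15, the partner of GDF9, was at 695 FPKM in the control and 634 FPKM in the SPE library, the oocyte-secreted protein gene OOSP2 at 904 and 730 FPKM, and the linker histone gene H1FOO at 169 and 170 FPKM. The 22 measured genes of meiotic cell cycle control had no member beyond 2-fold on the same scale (median -0.002, mean 0.09, percentile 79.2). MOS, the kinase that maintains metaphase II arrest, was at 469 and 486 FPKM. FBXO5, an inhibitor of the anaphase-promoting complex, was at 3.56 and 7.80 FPKM, and the spindle kinase gene AURKA at 2.44 and 5.02 FPKM, which are 2.19-fold and 2.06-fold higher in the SPE library without the pseudocount. CDC20, an activator of the anaphase-promoting complex, was at a log2 ratio of -0.54.

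None of the other lists for meiosis and early development held a measured member beyond 2-fold on the log2(FPKM + 1) scale. Members below a mean of 1 FPKM are not covered. The spindle and kinetochore list (14 measured genes) had a median of -0.09 at percentile 29.7, with TACC3 at 145 and 136 FPKM. The cohesin and meiotic chromosome list (7 genes) had a median of -0.02 and a mean of 0.03 at percentile 67.6. The actin and polar body extrusion list (11 genes) lay at 0.02 and percentile 72.6, and the cortical granule and fertilization list (7 genes) at 0.08 and percentile 75.2, where SNAP23 had the largest ratio (0.99; 1.29 and 3.54 FPKM, which is 2.75-fold without the pseudocount). Maternal mRNA clearance (16 genes) was at -0.07 and percentile 28.9, with BTG4, the adaptor of maternal mRNA deadenylation, at 382 and 369 FPKM. Dormant mRNAs recruited in maturation (12 genes) were at -0.07 and percentile 36.0. Of the subcortical maternal complex 3 genes were measured: OOEP at 24.2 and 31.4 FPKM, PADI6 at 6.14 and 5.38 FPKM and TLE6 at 4.47 and 2.64 FPKM. The list of 2-cell genes had 1 measured member, NELFA, at 1.73 and 1.58 FPKM. Only 2 replication-dependent histone genes were found in the table, and neither reached a mean of 1 FPKM.

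Of 25 genes of polyamine metabolism found, 11 were measured, and none of these differed by 2-fold. Of the 11, 3 were higher and 8 lower in the SPE library. The median was -0.06 at percentile 49.3 (0.0011 after removal of a running median over level). ODC1, the rate-limiting enzyme of polyamine synthesis, was at 15.9 FPKM in the control and 15.4 FPKM in the SPE library. AMD1, which supplies the aminopropyl donor for spermidine synthesis, was at 74.3 and 59.8 FPKM, and the antizyme gene OAZ1, which restrains ornithine decarboxylase, at 150.1 and 128.7 FPKM. SAT1, the acetyltransferase that starts polyamine breakdown, was at 2.75 and 5.06 FPKM (log2 ratio 0.69), the largest among the 11. EIF5A, the substrate of spermidine-dependent hypusination, was at 7.39 and 7.38 FPKM.

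The mitochondrially encoded genes were the only one of 27 lists with at least 5 measured members whose median stood apart from random lists. Those lists had the same size and were drawn by bins of level, which match this list only loosely. 10 of the 13 genes were higher in the SPE library and 3 lower, with a median log2 ratio of 0.10 at percentile 99.6. The median was 0.20 after removal of a running median over level, as genes of 100 FPKM or more had a median of -0.10. COX1 was at 26583 FPKM in the control and 32302 FPKM in the SPE library, ND3 at 3825 and 4355 FPKM, and ND4L at 2336 and 2012 FPKM. Genes on the mitochondrial chromosome held 62.7% of the summed FPKM in the control and 65.7% in the SPE library. They are cut from shared precursor transcripts and several share a locus in the table, so their differences are not independent. By chance 1.35 of 27 lists would stand apart, and against random lists not matched on level this list was at percentile 91.5. Its members had means from 1632 FPKM (ND4) to 41912 FPKM (ATP8), where few other genes lay. Only 134 of the genes analysed reached 100 FPKM. The percentile of 99.6 may therefore be in part a comparison with genes at much lower levels.

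**Figure D2:**
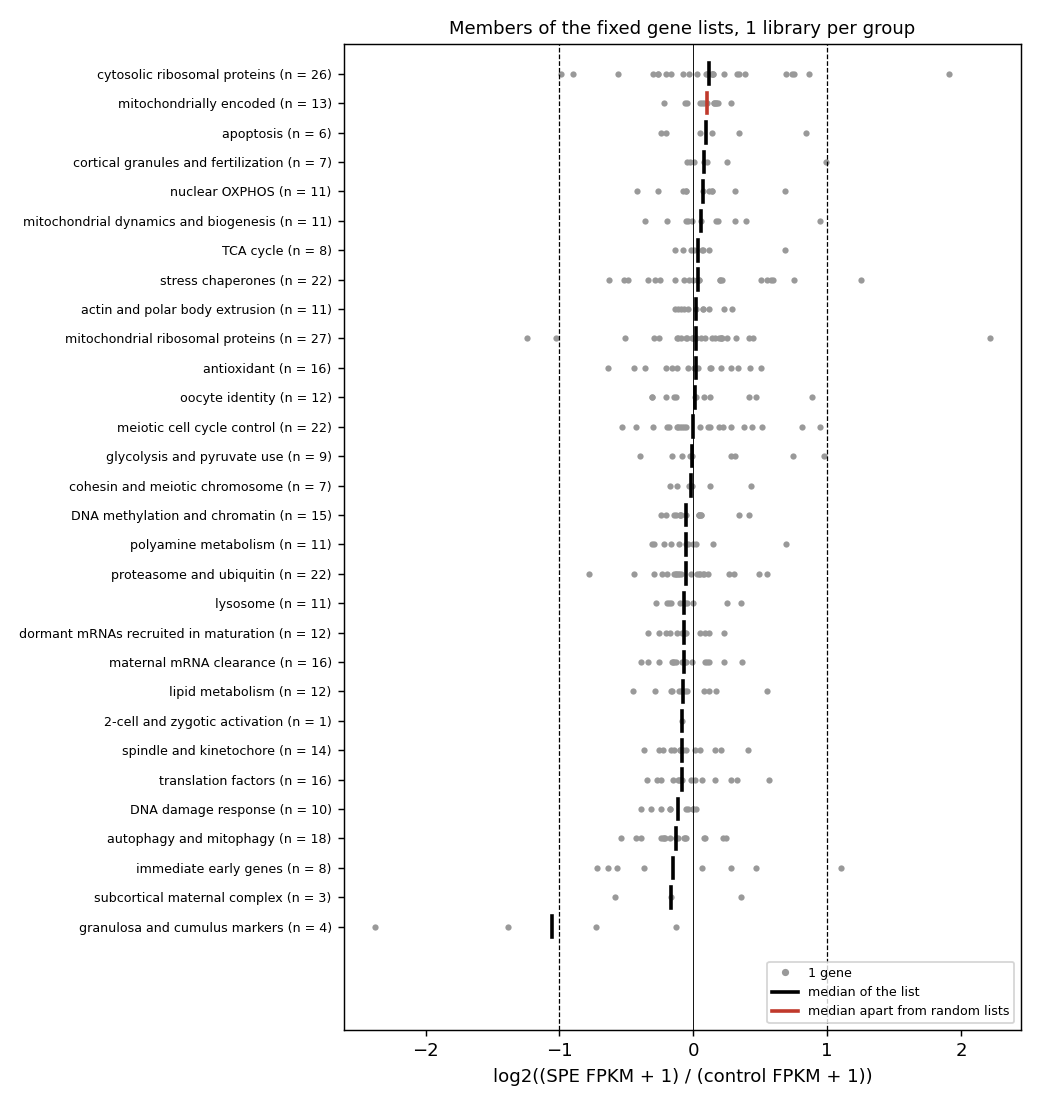
Each point is a measured gene of a list, placed by its log2 ratio of SPE to control FPKM, and each bar is the list's median; the number of measured genes stands beside each name. All medians of lists with at least 5 measured genes lie between -0.15 and 0.12, and that of the mitochondrially encoded genes (0.10) is drawn in red; 10 of the 27 medians change sign under at least 1 other scaling.

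The lists of nuclear OXPHOS genes, mitochondrial dynamics and biogenesis, antioxidants, autophagy and lysosome held no measured member beyond 2-fold on the log2(FPKM + 1) scale. Measured members were 11 of 59 found for nuclear OXPHOS, 11 of 30 for mitochondrial dynamics and biogenesis, and 16 of 39 for antioxidants. They were 18 of 42 for autophagy and mitophagy and 11 of 39 for lysosome, so most of each list is not covered. The nuclear OXPHOS list (11 genes) had a median of 0.08 at percentile 81.1, with cytochrome c, CYCS, at 71.5 and 79.0 FPKM. Mitochondrial dynamics and biogenesis (11 genes) lay at 0.06 and percentile 88.2, where TOMM22 was at 0.431 and 1.76 FPKM. The antioxidant list (16 genes) was at 0.02 and percentile 77.4, with SOD2, the mitochondrial superoxide dismutase, at 3.54 and 5.46 FPKM, and PRDX2, a peroxiredoxin, at 24.0 and 18.5 FPKM. In the autophagy and mitophagy list 14 of 18 genes were lower in the SPE library, with a median of -0.13 at percentile 6.48. The autophagy receptor gene SQSTM1 was at 30.5 and 26.1 FPKM, MAP1LC3A at 3.94 and 2.39 FPKM and BECN1 at 4.53 and 3.11 FPKM. The lysosome list (11 genes) was at -0.07 and percentile 32.1.

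For cell death and damage, the apoptosis list (6 measured of 31 found) had a median of 0.09 at percentile 88.6. The survival factor gene BCL2L1 was at 1222 and 1033 FPKM over a model of 608 bases, and MCL1 was at 1.02 and 2.62 FPKM. In the DNA damage response list 10 of 38 genes found were measured. Of these 10, 9 were lower in the SPE library, with a median of -0.11 at percentile 19.9 and PCNA at 774 and 744 FPKM. The stress chaperone list (22 genes) was at 0.03 and percentile 91.0. DNAJB9, a chaperone of the endoplasmic reticulum, was its 1 member beyond 2-fold, at 2.89 and 8.28 FPKM, and CHAC1 was at 4.89 and 8.93 FPKM, whereas DDIT3 was at 4.33 and 2.44 FPKM. Of 8 immediate early genes EGR1 was beyond 2-fold (1.24 and 3.81 FPKM), JUNB was at 2.10 and 0.883 FPKM, and the median was -0.15 at percentile 11.1 (0.053 on the TPM scale).

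Lists for protein synthesis, metabolism and chromatin had medians between -0.09 and 0.12. Cytosolic ribosomal proteins (26 genes) had a median of 0.12 at percentile 95.3. RPL29, listed at 0 in the control and at 2.77 FPKM in the SPE library, passed the size rule, while RPL10A was at 3.30 and 1.17 FPKM. Mitochondrial ribosomal proteins (27 genes) were at 0.02 and percentile 82.7. MRPL36 was higher by the size rule (0.166 and 4.42 FPKM), and MRPL40 (3.34 and 0.838 FPKM) was lower, as was MRPL51. Translation factors (16 genes) were at -0.09 and percentile 31.5, the proteasome and ubiquitin list (22 genes) at -0.06 and percentile 45.5, glycolysis and pyruvate use (9 genes) at -0.01 and percentile 50.5 with a mean of 0.18, and the TCA cycle (8 genes) at 0.04 and percentile 70.0. Lipid metabolism (12 genes) lay at -0.08 and percentile 23.6, and DNA methylation and chromatin (15 genes) at -0.05 and percentile 47.0, with DNMT1, the maintenance methyltransferase, at 166 and 154 FPKM.

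Markers of somatic cells of the ovary were low in both libraries. The granulosa and cumulus list summed to 33.1 FPKM in the control and 14.6 FPKM in the SPE library, and all somatic lists together made up 0.0138% and 0.00601% of the summed FPKM. Of 4 granulosa and cumulus genes with a mean of at least 1 FPKM, INHBB and HSD3B1 were beyond 2-fold. INHBB, the inhibin beta B subunit gene, was at 10.8 FPKM in the control and 1.28 FPKM in the SPE library over a model of 349 bases on an unplaced scaffold, and HSD3B1, a steroid synthesis gene, was at 1.90 and 0.111 FPKM. INHBA was at 9.87 and 5.55 FPKM and GATA4 at 4.13 and 3.70 FPKM. The 35 list members other than INHBB, INHBA and HSD3B1 summed to 10.5 and 7.62 FPKM, with 12 lower in the SPE library, 9 higher and 14 listed at 0 in both. With 4 measured members the list was not ranked among random lists. The highest marker of theca, stroma and endothelium was PECAM1, at 0.352 and 0.314 FPKM, and the highest of blood and immune cells was CD68, at 0.395 FPKM in the control and listed at 0 in the SPE library.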

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

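The alternatives with gene models of at least 3 kb, with genes above 0 in both libraries, and with other gene symbols were chosen after seeing the data. In every setting the higher genes outnumbered the lower, as they did by 125 to 94 as reported. The settings reuse the same 2 libraries, and in several the genes counted are a subset of those reported. This shared direction was therefore largely given and is no independent support. The counts moved with the pseudocount, to 238 higher and 168 lower at 0.1 FPKM and to 23 and 15 at 5 FPKM, and with the size rule, to 331 and 249 at 1.5-fold and to 25 and 19 at 4-fold. They were 226 and 158 with no filter, 17 and 7 at a mean of at least 10 FPKM, and 51 and 28 for gene models of at least 3 kb, where fewer genes entered. Scaling to TPM, which also lowers the effective filter and pseudocount, gave 612 and 444. Leaving out genes listed at 0 in either library gave 87 higher and 59 lower. The higher share was 57.1% as reported and 70.8% at a mean of at least 10 FPKM. Centring, upper quartile scaling and the running median kept both counts within 1.5 times, and no scaling shifted the median log2 ratio by over 0.1. The number of lists that stood apart was 1 as reported, 3 with no filter, 2 on the TPM scale and 2 with other gene symbols matched. The mitochondrially encoded genes stood apart in each of these. With no filter the cytosolic ribosomal proteins (percentile 99.8) and the granulosa and cumulus markers (0.61) joined them, and the latter also did on the TPM scale (0, median -0.75) and with KITLG matched (0.085, median -0.73), where more members entered. With random lists not matched on level, the cytosolic ribosomal proteins alone stood apart (percentile 98.5), and the cause was not tested. All 309 list medians under the alternatives moved by less than the SD of their members. This bound is loose, as that SD exceeded the size of the median in every list, and unmatched random lists cannot move a median. Of the 27 lists 10 changed sign under at least 1 scaling: oocyte identity, meiotic cell cycle control, cohesin, polyamine metabolism, stress chaperones, glycolysis, TCA cycle, proteasome, DNA methylation and immediate early genes. Spearman's rho was 0.90 over genes of at least 1 FPKM. Without the 100 highest genes the somatic share was 0.0758% in the control and 0.0341% in the SPE library. The alternative on CPM was not run, as the columns used hold no counts. No paired analysis was possible because each group had 1 matched library, and for the same reason no library could be left out. Absolute depth is unknown, so what it limits was not tested. The robust SD of the log2 ratio was 0.32 at 1 to 2 FPKM and 0.20 at 100 FPKM or more.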

Other observations

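The tests on expression level, gene model length and GDF9 were chosen only after the result was seen; those on granulosa and cumulus transcripts and on ATF4 targets were set before their values were computed, although 3 of the ATF4 targets belong to the stress chaperone list, whose values had been seen.

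Some abundant nuclear transcripts were picked here after their values were seen. UBB, a polyubiquitin gene, was at 3006 FPKM in the control and 3160 FPKM in the SPE library, HILPDA, a lipid droplet protein gene, at 1754 and 1564 FPKM, ACCSL at 1585 and 1454 FPKM, PCBP1, an RNA-binding protein gene, at 1557 and 1436 FPKM, and the transcriptional regulator gene ID3 at 885 and 914 FPKM. Of 17 families defined by symbol after seeing the data and with at least 5 measured members, none stood apart from random lists. Solute carriers (49 genes) had a median log2 ratio of -0.06, zinc finger genes named ZNF (46 genes) -0.02, which turned to 0.014 when centred on the median, kinesins (10 genes) -0.11 with 9 lower in the SPE library, and F-box genes of the FBXO type (10 genes) 0.20 at percentile 97.1. The medians of solute carriers, kinesins and FBXO genes kept their sign under all 5 scalings tried.

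Some genes under 10 FPKM outside the fixed lists had large ratios and were picked after their values were seen. IL10RB was listed at 0 in the control and at 16.2 FPKM in the SPE library over a model of 284 bases. RHOB, a small GTPase gene, was at 7.42 and 0.470 FPKM over 591 bases, and TIGD2 at 1.10 and 7.62 FPKM over 1517 bases. SHFM1, a proteasome-associated gene, was at 0.889 and 6.23 FPKM over 403 bases.

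The genes beyond 2-fold lay mostly at low level. The share beyond 2-fold was 6.01 times higher at 1 to 2 FPKM than at 30 FPKM or more, but this ratio restates the pattern, so noise of genes with few reads cannot be told apart from other causes by it. Among genes of at least 10 FPKM it was 6.13% for models under 3 kb (16 of 261) and 0.957% for longer ones (8 of 836), a ratio of 6.41. Short models that collect few reads would give such a ratio, but length was not separated from provisional naming. Established symbols made up 769 of these 1097 genes, but only 5 of the 17 higher and 1 of the 7 lower by 2-fold. An effect of spermidine on the genes beyond 2-fold stays open and was not tested, since each group had 1 matched library.

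INHBB, INHBA and HSD3B1 were lower in the SPE library, and a candidate explanation is carry-over of granulosa or cumulus cells with the control oocytes. The other 35 list members, none of which another fixed list holds, summed to 10.5 FPKM in the control and 7.62 FPKM in the SPE library, a ratio of 1.38 that lies between the bounds set for and against it (1.63 without GATA4, the highest of them, seen afterwards). Of these 35, 12 were lower in the SPE library, 9 were higher and 14 were listed at 0 in both, LGALS1 and KRT18 among the last. Picked after their values were seen, STAR was at 1.27 and 0.168 FPKM, CTGF at 1.14 and 0.166 FPKM, GJA1 at 0.708 and 0.0854 FPKM and CYP11A1 at 0.490 and 0.486 FPKM. Carry-over and lower expression in the oocyte cannot be told apart here. Only 3 of the 35 exceeded 1 FPKM in either library, and each group had 1 matched library.

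GDF9 was 1.86-fold higher in the SPE library, the largest ratio among the 12 measured oocyte identity genes. A rise of oocyte-specific transcripts as a whole by about as much as GDF9 (0.89) is argued against, since the other 11 had a median of 0.010 with an SD of 0.26. GDF9 was the largest of the 12, so that the others lie below it was given and carries no weight. Reads shared with an annotated neighbour are argued against too, as 0 genes of the table overlap its locus. Noise between single libraries and an effect of spermidine on GDF9 both stay open and were not tested. In the unmatched columns Con2 and SPD2, which may be second replicates, the order was the opposite, so the difference may not hold.

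MTHFD2, CHAC1 and DNAJB9, higher in the SPE library, are known stress-responsive genes, which raised the hypothesis of a joint rise of targets of the transcription factor ATF4. The test was negative for the measured targets of ATF4 and does not cover other stress responses. The 10 other measured genes of the target list, ATF4 among them, had a median log2 ratio of -0.05, at percentile 43.0 of random lists, and 7 of them were lower in the SPE library. Of 36 list members found only these 10 were measured, so the test does not cover the rest. In the stress chaperone list, which holds DNAJB9 and CHAC1, 13 of 22 genes were higher and 9 lower in the SPE library (percentile 91.0). A joint rise of stress genes outside the ATF4 targets was not tested. ATF4 was at 60.7 and 59.4 FPKM, which is a transcript level and does not measure the activity of the protein.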
